A study of Mus musculus with 284 samples.

How the data were processed

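The series holds single cell transcriptomes of tumour propagating cells from mouse skin tumours. Per the labels' protocols, mice received a single dose of the carcinogen DMBA at an age of 8 weeks and the tumour promoter TPA for more than 20 weeks, and tumours were dissociated with trypsin. Living cells with the surface markers CD34 and CD49f (integrin alpha 6) and a YFP reporter switched on by keratin 14-driven Cre were sorted into 96-well plates, and libraries were made with a modified Smart-seq2 protocol, per the labels' protocols. The 284 cells came from 4 mice: WT1 and WT2, labelled wild type, and KO1 and KO3, labelled Sirt6-/-. Each sample is a single cell, so the mouse was taken as the replicate, with 2 mice per genotype. The cells of KO1 lay on plate 1 (65 cells) and plate 2 (8 cells), those of KO3 on plate 2, those of WT1 on plate 3, and those of WT2 on plate 4 (81 cells) and plate 3 (7 cells). No plate held cells of both genotypes, so genotype and plate cannot be told apart.

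The deposited table holds expected counts per gene and cell made by the authors with STAR and RSEM on the mouse genome build mm10 (GRCm38), per the submitters' processing notes. The versions of these tools and the settings of the alignment are not given in the sources used here. Of the non-zero values 21.5% were not whole numbers, as an estimate that divides reads between similar genes gives. Such division matters for genes with near-identical copies, whose values are uncertain. The protocol keeps no molecular identifiers, so a count is a read and not a molecule, and intervals and floors given here cover counting error only. The labels name no strand setting, so antisense partners were not told apart. The table has 54247 gene IDs, of which 54156 matched the GENCODE M21 annotation of GRCm38 that supplied symbols and coordinates. The 91 unmatched IDs carried 0.0001% of the counts and stayed in the totals. No 2 cells had identical values (0 pairs), and the highest correlation between cells was 0.82. No deposited cell was left out. No doublet caller was run, since each well was sorted as a single cell and no total exceeded 1684464 counts.

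Total counts per cell lay between 523999 and 1684464 (median 1130412), and detected genes between 3235 and 8470 (median 6364). For comparisons of detection between mice, each cell was also thinned at random to 500000 counts. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals.

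The gene comparison of the genotypes summed the expected counts of all cells of a mouse, rounded the sums to whole numbers and used edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, and the quasi-likelihood test (glmQLFit, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 mice per genotype this fit has 2 residual degrees of freedom. Levels are given as TMM-scaled CPM of these sums, except for Sirt6, Tdg and the marker levels, which are CPM of the unscaled sums. A gene with a count of 0 in both mice of a genotype was given a fold bound from a floor of 3 counts over the group. Gene lists were tested with camera of limma 3.58.1 with the preset correlation of 0.01, with camera with an estimated correlation, and with fry, adjusted over the lists. With an estimated correlation, camera takes its p from the residual degrees of freedom of the fit, 2 for the genotypes. Few lists can pass then, so a call lost there need not come from correlated genes. Of 32 lists, 28 had at least 5 members past the filter and were tested. The 4 others (fibroblasts, endothelial cells, melanocytes and sex-linked genes) are given as values, and were tested where an alternative left at least 5 members. DESeq2 1.42.0 and limma-voom were run as alternatives.

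Co-variation of glycolysis genes was measured within each mouse. Values were log2(CPM + 1) per cell, and the linear trends on log10 total counts and on the number of detected genes were removed. Of the 22 glycolysis genes, the 17 with a count in at least 20% of the cells of every mouse were used. Their mean pairwise Pearson correlation was set beside 1000 random lists of the same size matched on mean expression. No p-value was made from cells. For each other gene detected in at least 20% of the cells of every mouse, the partial correlation with the glycolysis score (the mean z-score of the 17 genes) was taken in each mouse, turned into Fisher z, and tested over the 4 mice with limma (intercept, 3 residual degrees of freedom). Limma moderates the spread of each gene toward that shared by all genes. Its p-values thus rest mostly on the shared spread and not on the 3 degrees of freedom alone. The fixed lists were then tested on the moderated statistics with cameraPR at the preset correlation of 0.01, and with camera on the z values with an estimated correlation. For the intercept the latter rests on 3 residual degrees of freedom, with the same limit on calls. As a background, 20 random lists matched to the glycolysis genes were put in place of the score, and for the correlation with oxidative phosphorylation 1000 in place of either list. The same z values were compared between genotypes with limma.

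Cells were clustered with scanpy 1.11.5 and igraph 0.11.9 (Leiden, 2000 variable genes, 15 principal components, 15 neighbours, resolution 0.5) in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. A cluster was named only from fixed markers. Plots were drawn with matplotlib 3.10.9. The plate check compared the plates within KO1 and within WT2, beside 50 draws of as many cells at random from the main plate of the same mouse.

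The groups, the tests, the gene lists, the cell type markers, the rule for naming genes and most alternatives were fixed before the data were examined. The named genes are Sirt6; for the genotypes, the 12 genes with the lowest p in each direction whose values did not overlap between genotypes, given as values where the adjusted p missed the threshold; the 2 to 4 members of each list with the lowest p; the 12 highest and 12 lowest statistics among the glycolysis-correlated genes, with the same filling; and the 5 leading genes of each cluster by fold. Symbols that begin with Gm and a digit, end in Rik or hold -ps were left out of that rule. A gene that the rule named is not reported here. Tdg-ps, Gm9855 and Tdg were added after their values were seen.

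On simulated data with the spread between the real mice, the genotype test over 16567 genes recovered 18% of genes changed 4-fold and 54% of those changed 16-fold, with 8 false calls. With a dispersion of 0.02 it recovered 95% and 98%. The limma test on Fisher z, tested over 8000 simulated genes, recovered 95% of genes with a z of 0.3 and 100% of those with a z of 0.6, with 15 false calls. This last simulation drew the genes independently and with the same spread for all. Real z values share a score in each mouse, so it cannot show how many false calls the real test makes. The alternatives were other scalings, filters, tests, weights of cells, the main plate of each mouse alone, each mouse left out, and, for the co-variation, other covariates, thinning, a pseudocount of 10, detection in 50% of the cells and Spearman correlation. For the clusters they were resolutions of 0.3 and 1.0, thinning, and gene sets left out.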

Results

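Tumour propagating cells are the tumour cells able to start a new tumour after transfer, and the series asked whether a glycolytic subset of them drives squamous cell carcinoma. The data are 284 single cell transcriptomes of such cells from 4 mice: 69 cells of WT1, 88 of WT2, 73 of KO1 and 54 of KO3. SIRT6 is a chromatin-bound histone deacetylase known to repress glycolytic genes, and KO1 and KO3 carry the label Sirt6-/-. The summed counts were 77125493 for WT1, 92622682 for WT2, 81715648 for KO1 and 66335552 for KO3. The median cell had 1154325, 1048412, 1116804 and 1266650 counts in the same order of mice. The median numbers of detected genes were 7009, 5783.5, 6367 and 6614.5, and 6543, 5511, 6002 and 6154.5 after thinning each cell to 500000 counts.

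The cells were keratinocytes by their transcripts. Krt14 and Krt5, the keratins of basal epidermis, had counts in 100% of the cells, the epithelial transcription factor Trp63 in 97.5%, and Itga6 and Cd34, which encode the sorted surface proteins, in 91.9% and 72.9%. Sox9 was found in 82.7% of the cells and Vim, a mesenchymal filament gene, in 3.5%. Of the cells, 0 had counts for at least 2 fibroblast markers, 0 for endothelial and 0 for melanocyte markers, and 1 cell of WT2 did so for immune markers. Col1a2 and Dcn of the fibroblast list were at 0 in every mouse, while Fbln1 of that list lay at 210.23, 123.68, 205.9 and 206.12 CPM in WT1, WT2, KO1 and KO3 and Col6a1 at 30.02 CPM in WT1 and 0 in the others. Camera could test the fibroblast list only where more members passed the filter, and called it lower in the mice labelled Sirt6-/- without WT2 (adjusted p = 0.00226) but not without KO1 (0.786), without KO3 (0.504) or with no filter on low counts (0.343). The endothelial gene Egfl7 lay between 3.77 and 5.87 CPM, and the melanocyte gene Pmel reached 3.55 CPM. The macrophage gene Lyz2 had counts in 11 cells, all from WT2 (12.5% of its cells). Xist, transcribed from the inactive X chromosome, lay between 124.68 and 392.28 CPM, and no Y-linked gene exceeded 0.06 CPM. The median share of counts on ribosomal RNA, the mitochondrial genes mt-Rnr1 and mt-Rnr2 included, was 6.55% in WT1, 7.38% in WT2, 7.06% in KO1 and 5.12% in KO3. That of the remaining mitochondrially encoded genes lay between 1.27% and 1.88%.

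Sirt6 transcripts were found in the mice labelled Sirt6-/- at levels like those of the wild type. Sirt6 (ENSMUSG00000034748.16; GRCm38 chromosome 10, 81621785 to 81627797, minus strand) lay at 16.7 CPM in WT1, 25.2 in WT2, 27.0 in KO1 and 14.5 in KO3, or 21.0 ± 6.0 in the wild type and 20.8 ± 8.8 in the mice labelled Sirt6-/- (SD, n = 2; exact permutation test, two-sided, p = 1.0, with 0.333 the smallest p that 2 against 2 mice allow). Counts were found in 69.6% of the cells of WT1 (95% interval 57.3 to 80.1), 65.9% of WT2 (55.0 to 75.7), 69.9% of KO1 (58.0 to 80.1) and 68.5% of KO3 (54.4 to 80.5). After thinning, these shares were 59.4%, 65.9%, 63.0% and 64.8%. The level of the gene thus goes against the label, and KO1 and KO3 are called the mice labelled Sirt6-/- throughout, also where a direction is drawn. A count per gene cannot check a deletion of part of the gene, which would leave reads on the remaining exons.

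The first comparison asked which genes differ between tumour propagating cells of the genotypes. Spink5 and Casp14, known from late epidermal differentiation, lay higher in both mice labelled Sirt6-/- than in both wild-type mice. Spink5 (ENSMUSG00000055561.9; chromosome 18, 43963235 to 44022501), an inhibitor of epidermal proteases, lay at 199.79 and 121.5 CPM in WT1 and WT2 and at 594.84 and 660.29 in KO1 and KO3, a log2 difference of 1.97 (SE 0.31). Casp14 (ENSMUSG00000005355.9; chromosome 10, 78711991 to 78718294, within 5 Mb of Sirt6), the caspase of cornifying keratinocytes, lay at 2.99 and 3.25 against 18.43 and 25.05 CPM, a log2 difference of 2.80 (SE 0.391). In the other direction, the non-coding RNA H19 (ENSMUSG00000000031.16; chromosome 7, 142575529 to 142578143) lay at 21.96 and 26.07 CPM in the wild type and at 2.17 and 1.13 in the mice labelled Sirt6-/-, a log2 difference of -3.86 (SE 0.512). Tnc (ENSMUSG00000028364.15; chromosome 4, 63959785 to 64047015), which encodes the matrix protein tenascin C, went from 162.51 and 301.46 CPM to 46.88 and 40.88, a log2 difference of -2.40 (SE 0.372).

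Whether these differences passed depended on the test. Of 16567 genes, edgeR's quasi-likelihood test called 0, and all named genes had an adjusted p of 0.809. At an unadjusted p under 0.05 it had 848 genes, DESeq2 called 149 (35 higher and 114 lower in the mice labelled Sirt6-/-), and limma-voom 0. The genes called by DESeq2 included Casp14 (adjusted p = 2e-06), Spink5 (4.53e-06), H19 (4.53e-09) and Tnc (6.16e-07), and the remaining genes named for this comparison except Zfp78 (0.0676). Mice of the same genotype differed widely, with a common biological coefficient of variation of 0.72. Both mice labelled Sirt6-/- lay above both wild-type mice in 2798 genes and below them in 3076, together 35.5% of the genes, where chance orders give 33.3%. The other genes of the rule are given as values.

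Fabp4, a fatty acid carrier best known from adipocytes, lay at 0.86, 0.99, 9.14 and 37.9 CPM in WT1, WT2, KO1 and KO3, with counts in 5, 5, 12 and 11 cells. Of its counts 36.8% lay in 1 cell, and its log2 difference of 4.66 became 3.29 without KO3. In the cells of cluster 3, described below, it lay at 41.3 CPM against 2.0 in the other cells. The other 9 genes higher in the mice labelled Sirt6-/- had a count of 0 in both wild-type mice and rested on few cells. The fold bounds of this paragraph cover the counting of reads alone. They do not bound the difference between the genotypes, because the draw of cells and mice is not covered. Against the floor of 3 counts over the group, Zfp791 was at least 235.8-fold higher, Lrrn4cl at least 189.6-fold, Emid1 149.8-fold and Krt20 133.0-fold. Mkrn3 was at least 120.0-fold higher, Adgrb3 112.0-fold, AC124108.1 74.1-fold and Zfp78 64.2-fold. The bound for Degs2 was 242.7-fold, with 68.5% of its counts in 1 cell of the 4 that had any, and fell to 117.0-fold without KO3. Zfp791 had counts in 6 cells of KO1 and 3 of KO3, and Emid1 in 2 and 1. With 1 mouse left out, the bounds of these 9 genes ranged from 29.2 to 110.3-fold without WT2, 35.0 to 132.4 without WT1, 60.9 to 277.0 without KO3 and 68.2 to 397.5 without KO1, where leaving out a mouse with a count of 0 raises the floor. Fcgbp (ENSMUSG00000047730.17; chromosome 7, 28071236 to 28120862), a mucus-associated protein gene, lay at 45.49 and 71.04 CPM in the wild type, in 2 and 19 cells, and at 0 in both mice labelled Sirt6-/-, at least 2868.6-fold lower. With only the genes of at least 10 CPM in 2 mice, edgeR called Fcgbp lower (adjusted p = 0.0297). Serpina3g was at least 402.0-fold lower, Sec14l4 312.0-fold, Clca3a2 227.2-fold and Sectm1b 154.7-fold. These too rested on few cells of WT1 and WT2: 1 and 7 for Serpina3g, with 46.9% of the counts in 1 cell, 2 and 8 for Sec14l4, 2 and 7 for Clca3a2, with 55.3% in 1 cell, and 2 and 4 for Sectm1b. With 1 mouse left out, the bounds of the 5 genes at 0 in the mice labelled Sirt6-/- ranged from 69.3 to 1285.3-fold without KO1, 85.4 to 1583.3 without KO3, 141.9 to 3351.3 without WT1 and 161.2 to 2288.8 without WT2. The secreted protein gene Crispld2 lay at 48.86 and 101.39 CPM against 3.67 and 1.55, in 18, 32, 7 and 1 cells. Arntl, a core gene of the circadian clock, lay at 39.73 and 45.97 against 14.76 and 15.3 CPM (log2 difference -1.51). The log2 differences were -1.67 for the metalloreductase gene Steap4, -1.23 for Tenm4 and -1.97 for Pigv.

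Grouped by list, the basal keratinocyte programme lay lower in the mice labelled Sirt6-/-. Of 18 basal genes 17 had a negative difference (median log2 difference -0.63), among them genes for the anchorage of basal cells to the basement membrane: Col17a1 (-1.23), Itgb4 (-0.89), Lamb3 (-0.80) and Itgb1 (-0.74). Col17a1 lay at 1613.76 and 3175.56 CPM in WT1 and WT2 against 1179.66 and 857.9 in KO1 and KO3. The list fell by camera with the preset correlation (adjusted p = 1.66e-07), and the adjusted p = 0.681 with an estimated correlation. Genes of the response to TGF-beta were lower too, 14 of 15, with Tgfbr1 at -1.56, Tgfbi at -0.96, Itgav at -0.69 and Skil at -0.63 (camera, adjusted p = 0.000643, and adjusted p = 0.685 with an estimated correlation). All 8 measured genes of the mesenchymal transition had a negative difference (median -0.91), with Tnc at -2.40, Mmp14 at -1.04 and Sparc at -1.10 (camera, adjusted p = 0.00327, and adjusted p = 0.685 with an estimated correlation). Tnc was also the 1 member of these 3 lists past the threshold when adjusted over the list alone (adjusted p = 0.0162). Without KO3, the TGF-beta list was no longer called (0.137) and the mesenchymal list turned direction (0.954), and without WT1 the mesenchymal list had an adjusted p of 0.229. The basal list was called with every mouse left out in turn at the preset correlation.

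Respiratory and antioxidant genes lay higher in the mice labelled Sirt6-/-. Of 48 nuclear genes of oxidative phosphorylation 45 had a positive difference (median log2 difference 0.30), led by Uqcrq (0.82), Atp5l (0.59), Ndufa8 (0.57) and Cox7c (0.48). The list rose by camera (adjusted p = 3.5e-07, and adjusted p = 0.685 with an estimated correlation). Of 26 genes of glutathione and antioxidant defence 22 were positive (median 0.34), with Gsta4 at 1275.3, 636.23, 1548.23 and 2262.33 CPM in WT1, WT2, KO1 and KO3, Gstp1 at 0.82, Gsto1 at 0.59 and Sod1 at 0.34 (camera, adjusted p = 9e-05, and adjusted p = 0.685 with an estimated correlation). Ribosomal protein genes were positive in 73 of 86 with a small median of 0.13, with Rpl36al at 0.66 and Rps27l at 0.57, while the mean level of the list, at 8.21, 8.55, 8.53 and 8.51 log2 CPM in WT1, WT2, KO1 and KO3, did not part the genotypes (camera, adjusted p = 0.00176, and adjusted p = 0.837 with an estimated correlation). Counted as adjusted over the list alone, 0 members of these 3 lists passed edgeR's test, against 0 over all genes. Without KO3 these lists were not called (0.0522 for oxidative phosphorylation, 0.0569 for antioxidant and 0.0566 for ribosomal genes), and without WT1 the ribosomal list turned direction (0.893).

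Proliferation and differentiation genes went the same way as those of respiration but rested on single mice. Genes of the G2/M phase were positive in 35 of 48 (median 0.34; Ndc80 1.27, Mki67 0.73, but Cenpf -0.92) and genes of the S phase in 28 of 40 (median 0.23; Tyms 0.67, but Cdca7 -0.40). Camera gave an adjusted p of 0.0081 for G2/M and 0.0194 for S, and for each the adjusted p = 0.837 with an estimated correlation. Mki67 lay at 111.75, 91.61, 108.57 and 227.82 CPM, so that KO3 stood apart. Suprabasal genes were positive in 11 of 17, with the differentiation genes Ly6d at 1.06 and Krtdap at 0.89 (camera, adjusted p = 0.035, and adjusted p = 0.837 with an estimated correlation). Tgm3 of that list lay at 29.0, 2.51, 47.0 and 127.33 CPM. Adjusted over the list alone, 0 members of these 3 lists passed. Without KO3, the adjusted p was 0.606 for S, 0.162 for G2/M and 0.556 for suprabasal genes, the latter 2 with the direction turned. Without WT2 it was 0.461 for S, direction turned, and 0.707 for G2/M, and without WT1 0.893 for suprabasal genes. The suprabasal list also lost its call with DESeq2 (0.0709), limma-voom (0.0718) and no filter on low counts (0.197).

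Immediate early and dissociation stress genes, which respond within minutes to handling of tissue, were lower in 17 of 21 (median log2 difference -0.72; camera, adjusted p = 0.00153, and adjusted p = 0.721 with an estimated correlation). Their high values came from WT2: Egr1 lay at 536.02, 1568.08, 562.85 and 355.88 CPM in WT1, WT2, KO1 and KO3, Dnajb1 at 527.28, 1688.81, 515.21 and 410.25, and Fosb at 228.38, 528.87, 184.97 and 178.94. Without WT2 the adjusted p was 0.707, without KO1 0.0707 and without KO3 0.104. Hair follicle stem cell genes were lower in 6 of 10 (camera, adjusted p = 0.0304, and adjusted p = 0.685 with an estimated correlation), with Nfatc1 at -2.43 and Tbx1 at -1.38, and Postn at 206.54 and 16.9 CPM in the wild type, with counts in 3 cells of WT1 and 5 of WT2, and 0 in the mice labelled Sirt6-/-. The list of muscle and adipocyte genes was positive in 4 of 5 (camera, adjusted p = 0.035, and adjusted p = 0.685 with an estimated correlation). Adjusted over the list alone, 3 of its members passed (Fabp4, Tnnt3 and Ckm, each 0.0203), and 0 of the stress and hair follicle lists. The muscle genes Tnnt3 and Ckm stayed under 1 CPM, Tnnt3 detected in the wild type alone and Ckm in the mice labelled Sirt6-/- alone. The hair follicle list lost its call without KO3 (0.186) and WT1 (0.224), and the muscle and adipocyte list without KO3 (0.356), WT1 (0.224) and WT2 (0.397). With limma-voom and with the mean log2 value per cell, the adjusted p was 0.33 and 0.221 for the hair follicle list and 0.161 and 0.221 for the muscle and adipocyte list, which had 0.339 with no filter on low counts.

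Glycolysis genes as a group were not called between the genotypes. Of 22 genes 9 had a positive and 13 a negative difference (median log2 difference -0.02; camera, adjusted p = 0.984). The glucose transporter Slc2a1 lay at 347.46, 426.99, 285.33 and 264.74 CPM in WT1, WT2, KO1 and KO3 (log2 difference -0.49, SE 0.204), Pgk1 at 0.33 (SE 0.235) and Aldoc at -1.47 (SE 0.593). None passed when adjusted over the list alone (0 members, edgeR). The hypoxia response (adjusted p = 0.978; Car12 -0.47, Egln3 1.13), the pentose phosphate pathway (0.367; Pgd 0.54, G6pdx 0.55), the TCA cycle (0.978; Aco1 -0.45, Suclg2 -0.37), fatty acid oxidation (0.874; Eci1 -0.63, and Ppara at 0, 0, 0.14 and 0.77 CPM), lipid and cholesterol synthesis (0.0736; Srebf1 -0.48, Acaca 0.50) and the unfolded protein and integrated stress response (0.325; Shmt2 0.57, Pdia4 -0.35) were not called by camera either, with 0 members past the threshold adjusted over the list alone. Lipid synthesis was called without KO1 (0.000596) and without WT1 (0.00102), and also with a minimum of 10 CPM (0.0405) and after thinning (0.0454).

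The list of oncofetal genes known to be repressed by SIRT6 was not called (camera, adjusted p = 0.617). Its median difference was 0.33 while its mean (-0.49) and the direction of the test were negative, owing to H19, the 1 member past the threshold when adjusted over the list alone (adjusted p = 0.00535), while Igf2bp3 had a difference of 0.36. On the DESeq2 statistics camera called the list lower (adjusted p = 0.0404), and in the other settings its adjusted p lay between 0.229 and 0.928. Camera also left uncalled wound and tumour keratinocyte genes (0.293; Il24 -1.35, and Sprr1b at 111.69, 35.33, 145.72 and 382.97 CPM), squamous carcinoma propagating cell genes (0.474; Itgb1 -0.74, Itga6 -0.65), Notch (0.605; Notch2 0.47, Dll1 at 46.32, 84.74, 57.13 and 26.09 CPM), p53 targets (0.118; Bax 0.54, Pmaip1 0.73), interferon response (0.247; Psmb8 -1.78, Ifih1 at 5.44, 10.77, 0.59 and 0 CPM), MHC class II (0.978; H2-DMa -0.71, Cd74 at most 2.0 CPM), immune cells (0.898; Coro1a -1.23, Cd52 at most 0.8 CPM) and sebaceous gland genes (0.0904; Krt79 at 2.21, 0, 27.2 and 15.83 CPM and Pparg at 0, 0.3, 1.34 and 4.24), with 0 members of these lists past the threshold adjusted over the list alone. With 1 mouse left out, wound genes were called without KO1 (0.0264), interferon (0.0119) and immune genes (0.0177) without WT1, and propagating cell genes (0.004) and p53 targets (0.0147) without WT2. Other settings called wound genes with a minimum of 10 CPM (0.0278), sebaceous gland genes with no filter on low counts (0.0222) and after thinning (0.0318), and p53 targets with the mean log2 value per cell (0.0152). Of the 28 lists, camera called 12 at the preset correlation (7 higher and 5 lower), 0 with an estimated correlation and fry 0 (lowest adjusted p = 0.206). The estimated correlation was -0.049 for the basal list, below the preset 0.01, and its unadjusted p was 0.0243 (camera). Its lost call thus came with the fewer degrees of freedom. For some lists the estimate was higher, with 0.292 for oxidative phosphorylation and 0.758 for ribosomal proteins. Splitting the mice across the genotypes gave nearly as many calls: 11 lists for WT1 and KO1 against WT2 and KO3, and 10 for WT1 and KO3 against WT2 and KO1. Both splits called ribosomal, G2/M and immediate early genes. The former also called oxidative phosphorylation, suprabasal and hair follicle genes, and the latter antioxidant and S phase genes. Neither split called the basal, TGF-beta, mesenchymal or muscle and adipocyte lists. Without KO3, 1 list was called.

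**Figure D1:**
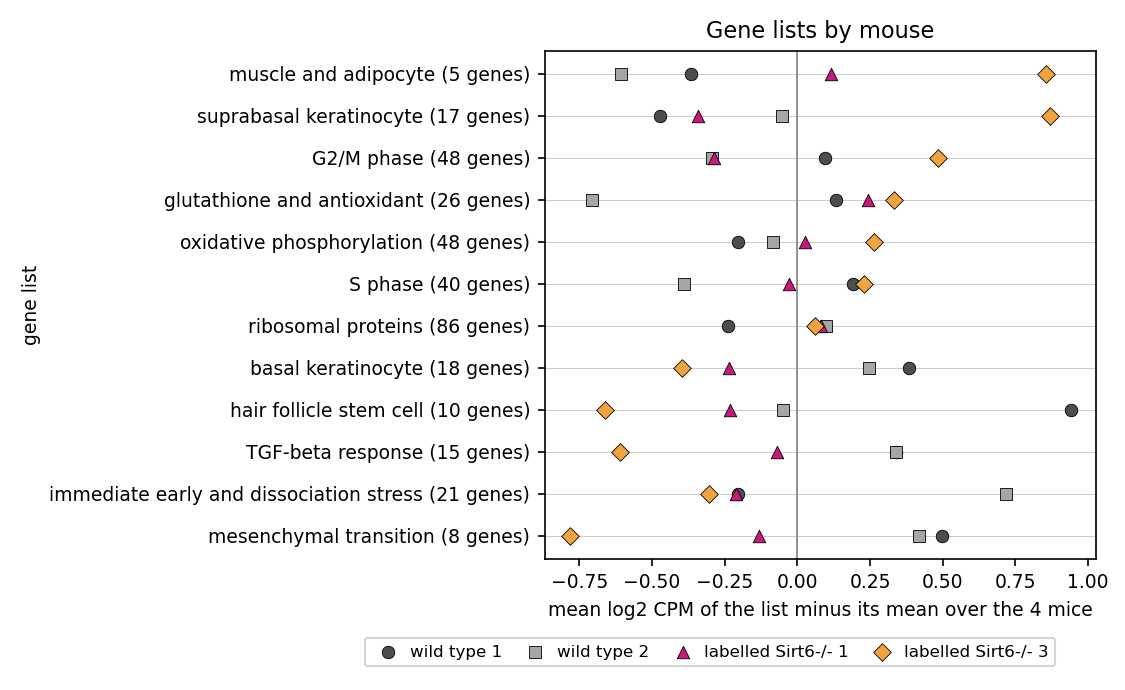
Mean log2 CPM of the members of 12 gene lists in each of the 4 mice, given as the difference from the mean over the mice (x axis, log2 units; lists on the y axis, 1 point per mouse). Basal keratinocyte genes lay lower in both mice labelled Sirt6-/-, oxidative phosphorylation genes higher, and WT2 stood apart in the immediate early and dissociation stress genes.

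The plates gave no genotype-free comparison, but 2 mice had cells on 2 plates. Between plates 1 and 2 of KO1, the log2 difference over 8528 genes had an SD of 1.4, above all 50 random draws of 8 cells from plate 1 (0.98 to 1.3). Between plates 3 and 4 of WT2, the SD was 1.2, and 48 of 50 draws of 7 cells were as large. The correlation across genes of these differences with the genotype difference was 0.05 in each, within the range of the draws (-0.11 to 0.15 in KO1 and -0.17 to 0.17 in WT2), where genes are not independent replicates.

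The second comparison asked whether glycolysis genes vary together from cell to cell within a mouse, as cells of a glycolytic subset would. The labels give no tumour number, so a mouse may pool several tumours. Differences between tumours could then not be told apart from those between cells. In each of the 4 mice the transcripts of most glycolytic enzymes varied together. Gapdh correlated with the remaining glycolysis genes at r = 0.74 in WT1, 0.47 in WT2, 0.60 in KO1 and 0.40 in KO3, and Ldha, which makes lactate from pyruvate, at 0.55, 0.63, 0.76 and 0.24. Pkm (0.64, 0.60, 0.69 and 0.32), Tpi1 (0.71, 0.41, 0.69 and 0.36), Pgk1 (0.70, 0.40, 0.52 and 0.60) and Aldoa (0.62, 0.56, 0.56 and 0.49) did likewise. The hexokinases Hk1 (-0.10 to 0.04) and Hk2 (-0.12 to 0.20), at the entry of the pathway, followed the others little, and Slc2a1 did so in WT1 (0.49), KO1 (0.29) and KO3 (0.30) but not in WT2 (-0.03).

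Over the 17 genes the mean pairwise correlation was 0.215 in WT1, 0.104 in WT2, 0.184 in KO1 and 0.136 in KO3 (mean 0.16, SD 0.049, n = 4 mice). Matched random lists had medians of 0.041, 0.018, 0.021 and 0.016, and their central 95% ended at 0.115, 0.071, 0.071 and 0.072. The glycolysis list stood at percentiles 100, 99.8, 100 and 99.9 of 1000 such lists. The random lists were matched on mean expression alone. The percentiles therefore do not show that glycolysis genes vary together more than those of other pathways. WT1 and KO1 were the higher mouse of either genotype, so the 4 values gave no order by genotype. Every mouse stood above percentile 99 in this setting and under each of the 9 alternatives that changed the cells, genes, values or covariates (lowest 99.4). Co-variation describes a range of levels between cells and sets no border around a subset.

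**Figure D2:**
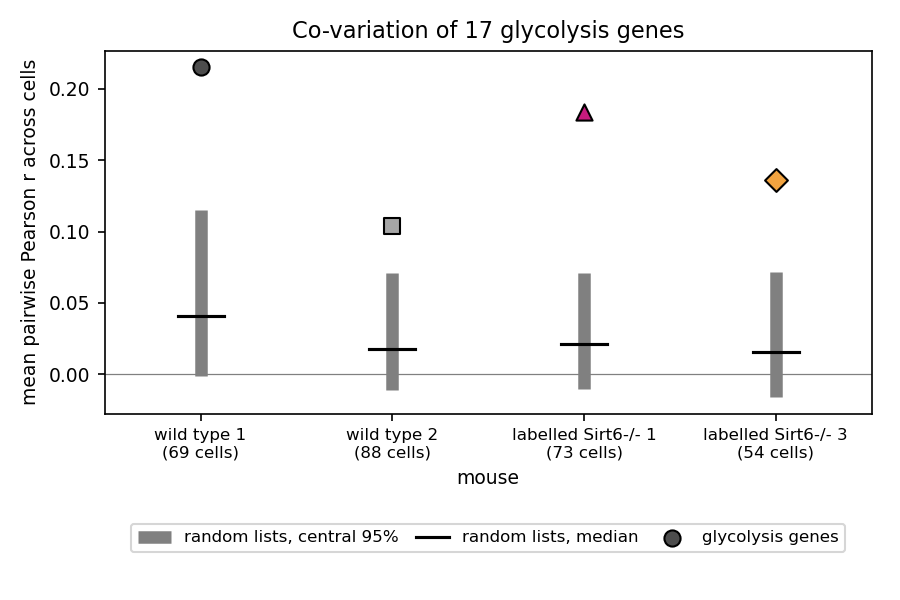
Mean pairwise Pearson correlation of the 17 glycolysis genes across the cells of each mouse (points, y axis), with the median and central 95% of 1000 matched random lists (bars). The 4 mice lay between 0.104 and 0.215, above the random lists.

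The genes that followed the glycolysis score from cell to cell included Hif1a, Bsg and Asns. Hif1a (ENSMUSG00000021109.13; chromosome 12, 73901375 to 73947530), the oxygen-regulated transcription factor that induces glycolysis, correlated with the score at r = 0.441 in WT1, 0.022 in WT2, 0.368 in KO1 and 0.36 in KO3 (limma over the 4 mice, adjusted p = 0.0259). Bsg (ENSMUSG00000023175.15; chromosome 10, 79704491 to 79711969), the chaperone of lactate transporters, did so at 0.363, 0.15, 0.397 and 0.392 (adjusted p = 0.00583), and Asns (ENSMUSG00000029752.12; chromosome 6, 7675169 to 7693254), asparagine synthetase, at 0.495, 0.208, 0.233 and 0.322 (adjusted p = 0.00945). Fam162a, a hypoxia-induced mitochondrial gene, had r of 0.549, 0.433, 0.126 and 0.432 (adjusted p = 0.000481), and the translation factor gene Eif5a 0.368, 0.612, 0.571 and 0.203 (adjusted p = 4.18e-05). The highest statistic belonged to Eno1b (adjusted p = 1.95e-07), a near-identical copy of the glycolysis gene Eno1 with which it can share reads, so its value is uncertain.

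Of 8457 genes, limma called 49, 48 positive and 1 negative. These p-values rest mostly on a spread pooled over the genes, not on that of each gene between the mice. An exact sign-flip test over 4 mice, not run here, could not go below 0.125. Prelid1 (adjusted p = 0.00462), Ywhaz (0.00659), Strap (0.00851), Rab31 (0.0164), Cnih1 (0.0242) and Phb2 (0.0259) completed the 12 highest. The negative gene was the nuclear non-coding RNA Malat1 (r = -0.156, -0.221, -0.383 and -0.265; adjusted p = 0.0469). The other negative genes of the rule missed the threshold: mt-Ts1 (0.0892), Gga2 (0.123), Zfp560 (0.142), Tbc1d25 (0.157), Fzd7 (0.165), Prc1 (0.173), Unc50 and Aurkb (0.176 each), Them5 (0.18), Panx1 (0.182) and Cnbd2 (0.186). A count of this size was not specific to glycolysis, since scores from 20 random matched lists called between 0 and 707 genes (median 290), at least 49 in 16 of 20. Hif1a, Rab31 and Cnih1 were called with 0 of the 20 random scores, Bsg, Strap and Asns with 1, Eno1b, Prelid1 and Phb2 with 3, Ywhaz and Malat1 with 4, Fam162a with 8 and Eif5a with 11. Without WT1, limma called 12 genes, and the adjusted p was 0.29 for Hif1a, 0.0973 for Bsg, 0.227 for Asns, 0.0785 for Fam162a and Ywhaz, 0.146 for Prelid1, Strap and Malat1, 0.329 for Rab31, 0.213 for Cnih1 and 0.353 for Phb2. Without KO1, it called 21 genes, and Hif1a (0.151), Bsg (0.061), Strap (0.0705), Cnih1 (0.0674), Ywhaz (0.238) and Malat1 (0.375) lost their call, without KO3 Hif1a (0.055), Cnih1 (0.0515) and Malat1 (0.0847), and without WT2, with 26 genes called, Malat1 (0.136). Hif1a also lost its call after thinning (0.0665), on the main plate of each mouse (0.053) and with ribosomal RNA and mitochondrial shares as covariates (0.0649). Rab31 did so after thinning (0.0665), Phb2 (0.0569) and Malat1 (0.0557) on the main plates, Ywhaz, Rab31 and Phb2 (0.0649 each) and Malat1 (0.166) with those shares as covariates, Malat1 with a pseudocount of 10 (0.0666), and Strap (0.313), Rab31 (0.0679), Cnih1 (0.176) and Phb2 (0.123) with Spearman correlation.

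By list, cells with a high glycolysis score also had high scores of wound and tumour keratinocyte genes. The keratins and envelope genes of injured or hyperproliferative epidermis, Krt6b (r = 0.136, 0.218, 0.261 and 0.136), Krt6a (0.076, 0.172, 0.267 and 0.147) and Sprr1b (0.119, 0.268, 0.08 and 0.151) among them, were positive in 8 of 8. Their score correlated with that of glycolysis at 0.247 in WT1, 0.444 in WT2, 0.225 in KO1 and 0.209 in KO3 (cameraPR, adjusted p = 0.000355, and adjusted p = 0.182 with an estimated correlation). A positive correlation of scores was not particular to this list. Random lists matched to the 48 oxidative phosphorylation genes, more than the 8 here, had medians of 0.404, 0.233, 0.375 and 0.241 in the same mice. Because the lists differ in size, these medians are no measure for the size of the wound correlation. Gene by gene, the median z was 0.153 for the wound list against 0.013 over all genes. Genes of the TCA cycle followed the score in 20 of 23, with citrate synthase Cs (0.226, 0.155, 0.42 and 0.276; adjusted p = 0.0367) and Sdha, and genes of the unfolded protein and integrated stress response in 14 of 16, with Asns and Hsp90b1 (each list adjusted p = 0.00364, and adjusted p = 0.182 with an estimated correlation). Lipid and cholesterol synthesis was positive in 15 of 18 (Lss, Scd1; adjusted p = 0.0115, and adjusted p = 0.632 with an estimated correlation) and the pentose phosphate pathway in 6 of 8 (Taldo1, G6pdx; adjusted p = 0.0197, and adjusted p = 0.632 with an estimated correlation). Below the other genes lay those of the G2/M phase, negative in 19 of 31 with the mitotic genes Aurkb and Tpx2 (adjusted p = 0.00107, and adjusted p = 0.182 with an estimated correlation), and ribosomal proteins, negative in 60 of 85 (adjusted p = 0.00897, and adjusted p = 0.906 with an estimated correlation). The ribosomal members of lowest p, Rps2 (0.191, 0.34, 0.219 and 0.05) and Rpl4 (0.203, 0.035, 0.275 and 0.131), were positive. Members that passed when adjusted over the list alone numbered 5 for pentose phosphate (4 positive, and Prps2 negative at 0.031, -0.212, -0.221 and -0.192), 3 for the stress response, 2 for the TCA cycle and 1 for wound genes, against 1 for the stress response (Asns) and 1 for the TCA cycle (Cs) over all genes.

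Hypoxia genes were positive in 7 of 8 and missed the threshold (adjusted p = 0.0994; Car12 at 0.291, -0.022, 0.453 and 0.038, P4ha1 at 0.284, 0.006, 0.138 and 0.172), and were called without WT2 (0.037), with a pseudocount of 10 (0.0369) and with ribosomal RNA and mitochondrial shares as covariates (0.0456). The other 11 of the 19 lists tested were not called: oxidative phosphorylation (adjusted p = 0.259, with 2 members past the threshold adjusted over the list alone), antioxidant (0.569), fatty acid oxidation (0.473), S phase (0.952), basal (0.673) and suprabasal keratinocyte (0.141), propagating cell (0.952), TGF-beta (0.66), Notch (0.307), p53 (0.473) and immediate early genes (0.722). The 20 random scores called between 4 and 13 lists (median 8.5), in the same direction for wound genes in 4 of 20, the TCA cycle in 10, the stress response in 4, lipid synthesis in 4, pentose phosphate in 7, G2/M in 3, ribosomal proteins in 1 and hypoxia in 0. Without KO1, pentose phosphate (0.109), lipid synthesis (0.253) and ribosomal proteins (0.109, direction turned) lost their calls, without WT1 pentose phosphate (0.318), and without WT2 lipid synthesis (0.179). The ribosomal call also ended after thinning (0.338) and with ribosomal RNA and mitochondrial shares as covariates (0.506). The glycolysis score correlated with the ribosomal RNA share at 0.08 in WT1, -0.11 in WT2, -0.30 in KO1 and -0.18 in KO3. With genes in 50% of the cells, pentose phosphate (0.119), the TCA cycle (0.0742), lipid synthesis (0.209) and G2/M (0.483) lost their calls, with Spearman correlation pentose phosphate (0.352) and the TCA cycle (0.107), with cell cycle scores as covariates G2/M (0.326), and with ribosomal RNA and mitochondrial shares lipid synthesis (0.053). With no covariates removed G2/M turned positive (6.06e-05), and S phase (1.27e-09, positive), TGF-beta (0.0348), Notch (0.0187) and immediate early genes (0.000221; these 3 negative) were called. Oxidative phosphorylation was called positive without KO1 (0.000495) and KO3 (0.00129) and after thinning (0.0243), suprabasal genes without KO1 (0.0475) and KO3 (0.00441), antioxidant genes without KO3 (0.0344) and basal genes without WT2 (0.0119). Random scores called these lists in the same direction in 17 of 20 for oxidative phosphorylation, 5 for suprabasal, 9 for antioxidant and 7 for basal genes.

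**Figure D3:**
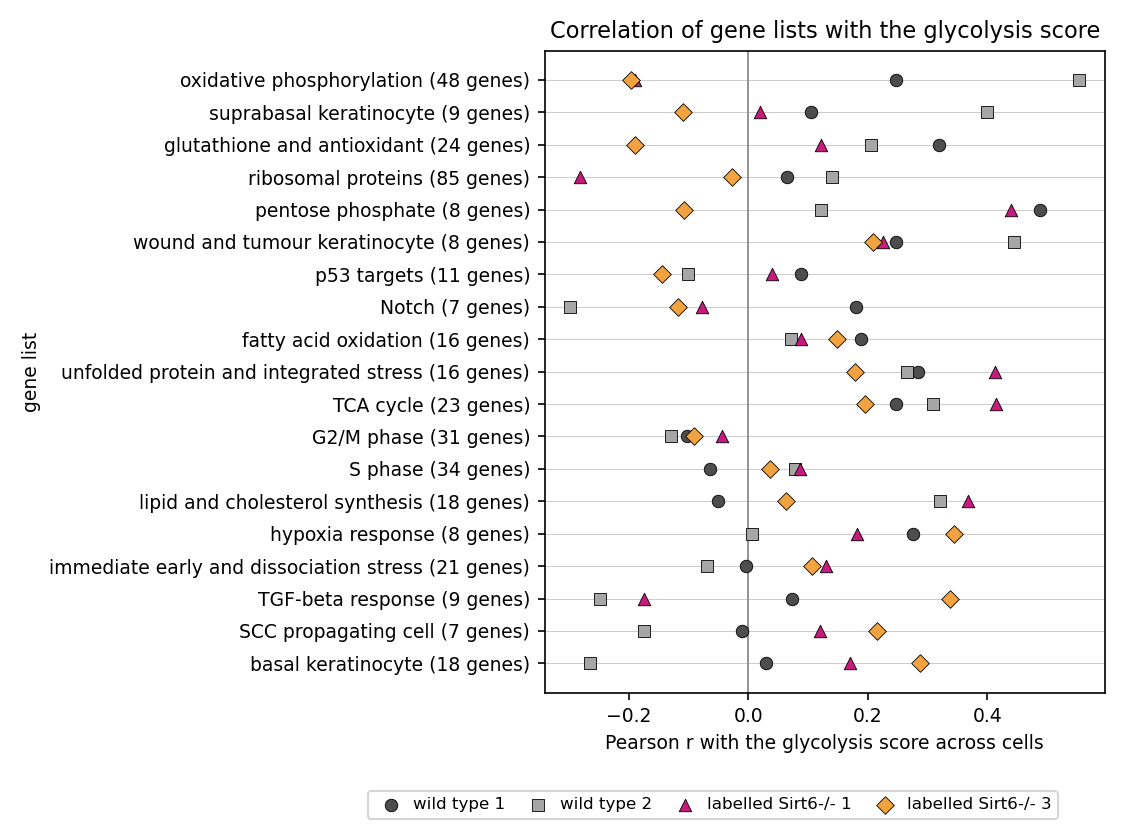
Correlation of the score of each of 19 gene lists with the glycolysis score across the cells of each mouse (x axis, Pearson r after removal of depth and detected genes; 1 point per mouse). The wound and tumour keratinocyte list was positive in all 4 mice (0.209 to 0.444), and oxidative phosphorylation was positive in WT1 (0.247) and WT2 (0.554) and negative in KO1 (-0.19) and KO3 (-0.196). Random lists of 48 genes, matched to oxidative phosphorylation and not drawn here, had medians of 0.233 to 0.404.

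The third question was which kinds of cells the sorted population held. The cells fell into 4 clusters. Cluster 1 (104 cells) was led by Pimreg, Cdca5, Fbxo5, Exo1 and Pask, had all 8 cycling markers at least 2-fold higher than the other cells, and was cycling-like. The other clusters stayed unnamed. Cluster 3 (62 cells) had 5 of 6 wound keratinocyte markers at least 2-fold higher, Krt6b among them, but was led by Tgm3, Krt13, Pla2g4e, Trex2 and Cyp4f39, of which Tgm3 belongs to the suprabasal list. Cluster 2 (81 cells) was led by Cldn1, Krt10, Sprr2a2, Ly6k and Scpep1, and cluster 4 (37 cells) by Matn4, Tspan18, Pxdn, Cxcl12 and Dlx3. Krt10 had counts in 34.6% of the cells of cluster 2 and in 49.3% of the other cells, so its lead came from the level in a minority.

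The clusters followed the mice. Cluster 2 held 79.5% of the cells of WT2 (95% interval 69.6 to 87.4) and 5.8% of WT1, 8.2% of KO1 and 1.9% of KO3. The cycling-like cluster held 56.5% of WT1, 15.9% of WT2, 38.4% of KO1 and 42.6% of KO3. Cluster 3 held 50.0% of KO3 (36.1 to 63.9), 24.6% of WT1, 19.2% of KO1 and 4.5% of WT2. Cluster 4 held 34.2% of KO1 (23.5 to 46.3), 13.0% of WT1, 5.6% of KO3 and 0 of 88 cells of WT2, which allows a share of up to 4.1%. In no cluster of this main run did both mice of a genotype stand apart from both of the other. With cell cycle genes left out, 1 cluster held 20.3% of WT1 and 4.5% of WT2 against 32.9% of KO1 and 35.2% of KO3. Clusters without overlap, in either direction, also occurred after thinning and at resolution 1.0. With 2 mice each the exact permutation test could not go below 0.333. The mean glycolysis score, over the 14 glycolysis genes not used for clustering, was taken where a cluster held at least 6 cells of a mouse. In the cycling-like cluster it was -0.03 in WT1, -0.19 in WT2, -0.02 in KO1 and 0.10 in KO3. In cluster 2 it was 0.04 in WT2 and 0.18 in KO1, in cluster 3 0.12 in WT1, 0.19 in KO1 and -0.07 in KO3, and in cluster 4 0.20 in WT1 and -0.13 in KO1, with SDs between cells of 0.34 to 0.72.

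**Figure D4:**
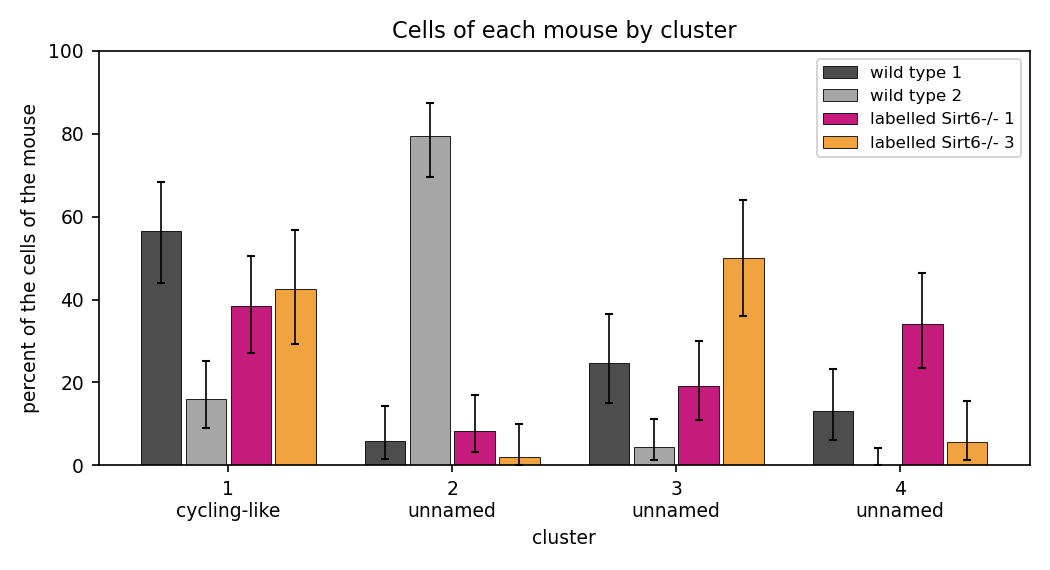
Percent of the cells of each mouse (bars, y axis) in each of the 4 clusters (x axis), with exact 95% binomial intervals for counting error. Cluster 2 held 79.5% of the cells of WT2 and at most 8.2% of those of another mouse.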

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

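The count of lists with opposite signs, the test by plate for WT2, the test around Sirt6, the test of Tdg cell by cell and the random lists beside oxidative phosphorylation were chosen after the results were seen, as were the alternatives with ribosomal RNA and mitochondrial shares as covariates and without stress genes. The correlation of some lists with the glycolysis score differed between the genotypes in a test of the difference itself (limma and cameraPR on the Fisher z of the 4 mice). In the mice labelled Sirt6-/- it was lower for oxidative phosphorylation (adjusted p = 1.17e-20), ribosomal proteins (7.39e-17), suprabasal keratinocyte (0.000193) and antioxidant genes (0.0113), and higher for basal keratinocyte (2.92e-07) and immediate early genes (0.0311). With an estimated correlation 0 lists passed (lowest adjusted p = 0.513). Among single genes 14 passed of 8457, 566 at an unadjusted p under 0.05. They included the respiratory chain genes Cox8a (r = 0.379 in WT1, 0.332 in WT2, -0.43 in KO1 and -0.253 in KO3; adjusted p = 0.00057), Cox4i1 (0.00448), Ndufa3 and Uqcr10 (0.0138 each) and Cox7a2 (0.0403), the nucleoside diphosphate kinases Nme1 (0.00979) and Nme2 (0.0289), and Plec, which had the higher correlation in the mice labelled Sirt6-/- (0.0403). Every mouse of a genotype had a sign opposite to every mouse of the other for 4 lists, with a difference between mean correlations, Sirt6-/- labelled minus wild type, of -0.594 for oxidative phosphorylation, -0.257 for ribosomal proteins, 0.261 for squamous carcinoma propagating cell genes and 0.154 for immediate early genes. Signs were counted in the main run alone, not in the alternatives, and however small the correlation. The opposite signs of single lists were not tested as such, only their number.

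The first pattern is that the glycolysis score had a positive correlation with oxidative phosphorylation in the wild type and a negative one in the mice labelled Sirt6-/-, with a gap of 0.436 between the lowest wild-type and the highest other correlation. The tables argue against depth as the cause, since the gap was 0.493 with every cell thinned to 500000 counts, and against RNA quality as measured by ribosomal RNA and mitochondrial shares, since it was 0.419 with these as covariates. A positive correlation was not specific to glycolysis, since 1000 random lists in its place had medians of 0.577 in WT1, 0.374 in WT2, 0.136 in KO1 and 0.261 in KO3, among which glycolysis stood at percentiles 5.2, 89.4, 11 and 4.8, and 26 of them had a gap as large, against 0 of 1000 random lists in place of oxidative phosphorylation (medians 0.404, 0.233, 0.375 and 0.241). Chance stays open, since the gap was 0.077 with WT1 at -0.024 by Spearman correlation. With 2 against 2 mice no exact p could go below 0.333. In the main run 4 of 19 lists had opposite signs, where a chance of 1 in 8 per list gives 2.4 (range 0 to 5). That range cannot decide, because it takes signs as even and lists as independent. The random lists above leaned positive, and ribosomal and oxidative phosphorylation scores ran together. Splitting the mice across the genotypes called 0 genes in each case and 3 or 5 lists, against 14 genes and 6 lists between the genotypes. Oxidative phosphorylation had an adjusted p of 0.0456 and 0.107 in these splits, against 1.17e-20 (cameraPR). The list was flagged for its difference between the genotypes, so weaker values in the other splits are built in. The splits therefore cannot decide on chance. A change in the coupling of both pathways with the genotype stays a hypothesis only, and genotype and plate cannot be told apart.

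The second pattern is the cluster that held 79.5% of the cells of WT2, though at resolution 1.0 the largest WT2 cluster held 39.8% of them, and at 0.3 70.5% together with 31.5% of the cells of KO1. The tables argue against plate 4 as its source, since 71.4% of the WT2 cells on plate 3 (5 of 7, 95% interval 29.0 to 96.3) and 5.8% of the WT1 cells on that plate (4 of 69, 1.6 to 14.2) fell in it. They also argue against total counts, with 70.5% of WT2 cells in such a cluster after thinning, and against stress genes as the whole source, with 72.7% when those were left out of the clustering. The number of detected genes was not tested as a source. After thinning it was still lowest in WT2 (median 5511, against 6002 to 6543 in the other mice). Before thinning, the medians of clusters 1 to 4 were 6835.5, 5547, 7028.5 and 5402. No biological explanation was tested, because no group of the design sets 1 mouse apart. A tumour of this mouse with a character of its own is a candidate explanation and stays a hypothesis.

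The third pattern, chosen after its values were seen, is that Tdg-ps (chromosome 15, 82516311 to 82519278) lay at 3.6, 2.4, 59.9 and 54.8 CPM in WT1, WT2, KO1 and KO3 and Gm9855 (chromosome 10, 42054113 to 42055306) at 5.0, 2.3, 46.9 and 40.8, both pseudogenes of the DNA repair gene Tdg (chromosome 10, 82629828 to 82650799). If reads of Tdg were counted on the pseudogenes, Tdg itself would be lower in both mice labelled Sirt6-/-. It was not lower in both (203.5, 92.3, 110.8 and 108.3 CPM; ratio of means 0.74), but the wild-type mice differed by more than that, 147.9 ± 78.6 (SD, n = 2), so its level could not decide. Cell by cell, Tdg-ps followed Tdg at r = 0.97 in KO1 and 0.94 in KO3 against 0.36 and 0.54 in the wild type, and the highest r of Tdg with other genes was 0.55 and 0.66. A variant Tdg allele, 1.0 Mb from Sirt6 and inherited with it, may divide its reads this way; 1.66% of genes within 5 Mb of Sirt6 against 0.89% of others were called by DESeq2 (3 genes near Sirt6, among them Casp14; ratio 1.86, Fisher's exact test, two-sided, p = 0.223), too few to decide whether the region carries another haplotype.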

How the results depend on the processing

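Chosen after the data were seen were the alternatives with ribosomal RNA and mitochondrial shares or genes removed, cell cycle covariates for the co-variation, stress genes left out of the clustering, an estimated correlation for the glycolysis-correlated lists, and each mouse left out for Sirt6, the fold bounds and the co-variation. For the genotypes, edgeR's count of 0 genes became 1 with a minimum of 10 CPM in 2 mice, and DESeq2 called 149, while the other settings called 0. Camera's 12 lists became 0 with an estimated correlation and 0 with fry, and between 1 and 13 with 1 mouse left out; a lone mouse was then assumed to vary like the other genotype. Among called lists, 137 alternative values kept direction and call, 24 lost the call and 5 turned: ribosomal proteins without WT1 (adjusted p = 0.893; with 1 mouse left out 3.01e-12 to 0.893), S phase without WT2 (0.461; 1.94e-06 to 0.606), and, without KO3, G2/M (0.162; 5.47e-09 to 0.707), suprabasal (0.556; 0.00294 to 0.893) and mesenchymal genes (0.954; 0.00294 to 0.954). The basal list was called in all 14 alternatives at the preset correlation, but not with an estimated one (0.681) or by fry. For named genes of the genotype comparison, 298 alternative values kept their side and 24 became calls. Of the fold bounds with 1 mouse left out, 34 moved by over 1.5 times and 22 did not. The co-variation of glycolysis genes, mean 0.16, became 0.244 with no covariates removed and stayed within the spread between mice otherwise; leaving out a mouse moved neither it nor Sirt6 beyond that spread. The 49 glycolysis-correlated genes became 2131 with no covariates, 20 after thinning, 28 on the main plates, 27 with a pseudocount of 10, 15 with ribosomal RNA and mitochondrial shares as covariates, and 12 to 53 with 1 mouse left out. Of their named genes, 236 values were the same, 36 lost and 5 gained a call, and Prc1 (z of 0.129) and Aurkb (0.2) turned with no covariates. The 7 lists became 11 with no covariates, 3 with genes in 50% of the cells and 0 with an estimated correlation; 68 values of called lists were the same and 14 lost the call. G2/M turned with no covariates (adjusted p = 6.06e-05) and ribosomal proteins without KO1 (0.109; 1.18e-06 to 0.109 with 1 mouse left out). The gap between genotypes in the correlation with oxidative phosphorylation moved in 2 settings of 8. The 4 clusters became 9 at resolution 1.0, and the share of WT2 cells in their main cluster moved in 2 of 5 settings (39.8% at resolution 1.0 and 69.3% without cell cycle genes). The cause was not tested for these changes. A minimum of 2000 genes and 100000 counts removed 0 cells, so it tests nothing. No paired analysis was possible because the labels give no link between single mice of the genotypes. At this depth a count of 0 in a mouse bounds a level only by the floor of 3 counts, which covers the reads of the sampled cells alone.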

Other observations

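Nothing in this part rests on a test, and its values were looked at after the main results. Within each mouse, the scores of basal and of differentiated keratinocytes ran against each other. The basal keratinocyte score, which includes Krt5, Krt14 and the integrins, ran against the suprabasal score at r = -0.75 in WT1, -0.78 in WT2, -0.64 in KO1 and -0.78 in KO3. The suprabasal score went with the wound and tumour keratinocyte score, which includes Krt6a and Sprr1b, at 0.60, 0.54, 0.61 and 0.70. Lipid and cholesterol synthesis genes went with wound genes at 0.42, 0.45, 0.40 and 0.33 and against basal genes at -0.32, -0.35, -0.33 and -0.30. S phase genes ran against wound genes in each mouse, at -0.40, -0.10, -0.41 and -0.54. Ribosomal protein and oxidative phosphorylation genes formed the pair with the highest mean correlation of those computed, 0.83, 0.67, 0.79 and 0.77.

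The score of p53 targets went with that of antioxidant genes at 0.37 in WT1, 0.18 in WT2, 0.40 in KO1 and 0.21 in KO3. Immediate early genes ran against oxidative phosphorylation genes at -0.23, -0.29, -0.38 and -0.08. These are correlations across cells within a mouse after removal of depth, and the cells of a mouse are not independent replicates.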
